A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

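Whole-cell total RNA from 3 wildtype and 3 set4 deletion libraries of Saccharomyces cerevisiae BY4741 was depleted of ribosomal RNA with a Ribo-Zero kit and made into stranded TruSeq libraries, per the labels' protocols. Cells grew in YPD at 30 °C to mid-log phase, per the labels. Nothing in the labels says that the replicates came from separate cultures. The submitters' processing notes name FastQC (read quality), Trimmomatic (read trimming), BWA (alignment), StringTie (transcript assembly and quantification) and DESeq2 (differential expression), and the build sacCer3. The purposes in brackets are what each tool is generally used for. The notes used here give no order, role, version or setting, and the counting step, filters and strand setting are not given in the sources used here.

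Values deposited by the authors are a log fold change per transcript, per the file headers, and are read here as log2 fold changes although no base is named. Base 2 was taken because the submitters name DESeq2, which reports log2 values. If the values were natural logs, every fold would be larger and no sign or rank would differ. The header also does not name the numerator. The value of SET4 was used to read the direction as deletion over wildtype, so SET4 is no independent check of the labels, and every direction in the text rests on that reading. The table has 8630 lines after its header, of which 8626 held a value and 4 were empty in the copy used here. It holds no counts, levels, errors or p-values, and 0 columns of per-sample values were left unmapped. Depth per sample is therefore unknown and no precision can be attached to a single value. Whether low-count fold changes were shrunken is not given in the sources used here; values such as 29.17 for MSTRG.3067.1 in the authors' deposited table can arise where a genotype has no reads, and the table does not say which ones do.

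The tests fixed before the data were examined needed counts and could not be run. These tests, not run here, were edgeR's quasi-likelihood test per gene with an adjusted p under 0.05, camera and fry on the gene lists and on the genes near chromosome ends, the similarity of the libraries, the shape of the p-values and the share of mitochondrial counts. In their place the table was described. The rule for named genes had asked for genes past the threshold and separated in all libraries; those conditions could not be applied. Instead the 10 highest and 10 lowest coding genes were named, leaving out multi-copy families as planned, and the same number among genes of at least 1000 coding nt without an intron or near-identical copy. Up to 4 members per list, those furthest from 0, were named. This form of the rule, the second group, the random lists and the gene properties they were matched or filtered on were chosen after the values were seen. The 34 gene lists, the distance of 20 kb from a chromosome end, its alternatives of 10 and 30 kb and the removal of named families there were fixed before the data were examined.

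Identifiers were matched by systematic name to the reference R64 annotation, whose assembly is that of sacCer3. Of 6021 protein-coding genes in the reference, 5823 had a value. Coordinates, coding length, introns, GC content and distance to the chromosome end come from that annotation and count from 1. Codon adaptation was computed from each gene's codons with weights from the ribosomal protein genes and served as a stand-in for expression level, which the table does not hold. A near-identical copy was a BLAST hit (BLAST+ 2.17.0) to another gene of at least 90% identity over at least 50% of the coding length. The 1918 transcripts that StringTie-style names mark as assembled have no coordinates in the table and were described as a class only.

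For each list the median over coding genes with a value was set against 10000 random lists of equal size, drawn to match the list's genes on 5 classes of coding length and 5 of codon adaptation, of equal numbers of genes, with SET4 left out. A median at or under percentile 2.5 or at or over percentile 97.5 was described as standing apart. Lists needed 4 members with a value: the strain marker list had 1 besides SET4 and the list of genes encoded by the mitochondrial genome had 0. Such a percentile treats genes as independent, while genes of a regulon vary together between cultures, so it is not a test of genotype. Genes whose midpoint lies within 20 kb of a chromosome end were handled in the same way. The procedure was checked on simulated lists of 30 genes, with 200 lists per shift and 1000 random lists each. They were drawn from the 5822 values of the comparison of deletion against wildtype, shuffled within the classes of length and codon adaptation. Genes in such lists do not vary together, unlike those of a regulon. With no shift added, 4.5% fell at the low side and 3.0% at the high side. A shift of 0.05 put 78.5% at the high side and shifts of 0.1 and 0.2 put 100% there.

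Shares have 95% Wilson intervals, and differences of medians 95% bootstrap intervals from 2000 draws. Alternatives tried were other matching (length only, GC with codon adaptation, none), means, lists without intron-containing genes, without genes with near-identical copies and with coding length of at least 1000 nt, another zero point (the median of the class of genes with the highest codon adaptation), thresholds of 1.5-fold and 1.2-fold, natural logs, and distances of 10 and 30 kb. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.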

Results

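Total RNA of the haploid laboratory yeast strain BY4741 was depleted of ribosomal RNA and sequenced as stranded libraries from 2 genotypes. There were 3 wildtype libraries and 3 libraries of a strain in which SET4 was deleted, all from mid-log cultures in rich YPD medium at 30 °C without added stress. SET4 encodes a protein with a SET domain, the fold found in many histone methyltransferases. The authors' deposited table held 1 log fold change for each of 8626 transcripts, among them 5823 protein-coding genes of the reference annotation. It held no column per library, so the depth of each library is unknown, and no fold change below has an error, an n or a p-value of its own. All values are read as log2 of the deletion over wildtype. The header names neither the base nor the direction, and both readings are explained with the processing.

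The comparison asks which transcripts differ between the deletion strain and wildtype; the table gives the size of each difference, and no transcript could be tested. SET4 itself (YJL105W, chromosome X, 225055 to 226737 of the sacCer3 assembly, a single exon of 1683 coding nt) had a value of -10.19 in the authors' deposited table, the lowest of any protein-coding gene. Its neighbours on either side were IME2, a meiotic kinase gene at -0.07, and PAM16, which encodes a mitochondrial import subunit, at -0.19 in the authors' deposited table. GSM1 and MEF2, the next genes beyond PAM16, stood at 0.09 and -0.0015 in the authors' deposited table. HIS3, whose product acts in histidine synthesis, had a value of -0.04 in the authors' deposited table. The other strain marker genes that had been listed, LEU2, URA3 and MET17, are not analysed here.

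Most protein-coding genes lay close to 0. The size of the value was under 0.1 for 75.1% of the 5823 genes, and the median size was 0.053. At 2-fold or more, 35 genes lay higher and 35 lower in the deletion, SET4 included. Leaving out SET4, the counts were 22 higher and 31 lower among genes without a near-identical copy, 8 and 5 among genes of 1000 nt or more, and 59 and 60 if the values are natural logs. At 1.5-fold or more the numbers were 69 higher and 74 lower. The medians of the 16 nuclear chromosomes ran from -0.0060 to 0.011.

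Targets of the general stress response and 3 lists of carbon source use and sugar transport lay above the other genes. The targets of Msn2 and Msn4, the transcription factors of the general stress response, had a median of 0.16, with 46 of 49 genes positive. Their members furthest from 0 were GPH1 at 0.42, HXK1 at 0.32, SPG4 at 0.31 and PGM2 at 0.29 in the authors' deposited table; GPH1 encodes glycogen phosphorylase, HXK1 a hexokinase and PGM2 a phosphoglucomutase. Genes of gluconeogenesis, the glyoxylate cycle and acetate use had a median of 0.12 (20 of 29 positive), with SFC1, a mitochondrial succinate-fumarate carrier gene, at 0.82, the fatty acid thiolase gene POT1 at 0.60, the lactate permease gene JEN1 at 0.25 and CRC1 at 0.25 in the authors' deposited table. Enzyme genes of the list, looked up after the values were seen, lay on both sides of 0, with MDH2 at 0.19, ACS1 at 0.14, IDP2 at 0.13, FBP1 at -0.15 and MLS1 at -0.24, and with PCK1 at -0.03 and ICL1 at -0.0063 near 0, in the authors' deposited table. Hexose transport genes had a median of 0.088 (13 of 22 positive) and genes of galactose and maltose use 0.082 (13 of 19 positive), the 2 lists sharing 1 gene. Each of the first 3 medians lay above those of all 10000 random lists of equal size, matched on coding length and codon adaptation, and galactose and maltose use lay at percentile 99.98.

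The hexose transport list was mixed, and without the 8 genes that have a near-identical copy its median was 0.045 over 14 genes, at percentile 98.3. The glucose transporter genes HXT1 and HXT3, looked up after the values were seen, stood at -0.10 and -0.15 in the authors' deposited table. Other members without a copy included HXT5 at 0.44, HXT8 at 0.38, MTH1 at 0.28, HXT4 at 0.23 and HXT2 at 0.08 in the authors' deposited table. On the other side stood RGT2 at -0.15 and HXT14 at -0.14 in the authors' deposited table. HXT6 at 0.38 and HXT7 at 0.36 in the authors' deposited table each have a near-identical copy. HXT13 stood at 1.48, HXT15 at -1.37, HXT11 at 1.14 and HXT16 at -0.59 in the authors' deposited table, and all 4 have a near-identical copy elsewhere in the genome, so reads may have been split between copies. Among maltose and galactose genes, MAL12 stood at 0.33, the galactose permease gene GAL2 at 0.28, the maltose activator gene MAL33 at 0.22 and the galactokinase gene GAL1 at 0.21 in the authors' deposited table.

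Phosphate and iron genes also lay above the other genes. The phosphate regulon had a median of 0.086, with 20 of 25 members positive, above all random lists. PHO89, a sodium-phosphate cotransporter gene, had 0.40, SPL2 0.35, the acid phosphatase gene PHO5 0.32 and PHO11 0.24 in the authors' deposited table. The iron regulon had a median of 0.046 (25 of 30 positive, percentile 99.3), led by the siderophore transporter gene ARN2 at 0.44 and the cell wall mannoprotein genes FIT1 at 0.34, FIT2 at 0.33 and FIT3 at 0.28 in the authors' deposited table. With means in place of medians the phosphate list lay at percentile 97.4, just inside the middle 95% of random lists.

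The seripauperin (PAU), DAN and TIR genes, which encode cell wall mannoproteins mostly made under low oxygen, had the highest median of any list, 0.22, with 23 of 30 positive and a median above all random lists. PAU19 stood at 3.69, PAU13 at 1.96, PAU21 at 1.35 and PAU22 at 1.28 in the authors' deposited table. Of the 30 genes 23 have a near-identical copy, including these 4, so their single values are uncertain. The 7 members without such a copy were all positive, with a median of 0.25, again above all random lists. They were singled out after the values were seen, and they include DAN1 at 0.98, PAU5 at 0.82 and TIR4 at 0.27 in the authors' deposited table. PAU5 is the only PAU gene among them, and the rest are DAN and TIR genes.

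Genes for making ribosomes lay below the other genes. Ribosome biogenesis genes had a median of -0.097, with 53 of 56 negative, and cytosolic ribosomal protein genes had a median of -0.077, with 91 of 103 negative. Both medians lay below those of all 10000 matched random lists. The biogenesis genes furthest from 0 were NSR1, a nucleolar protein gene, at -0.21, the RNA helicase gene DBP2 at -0.17, NHP2 at -0.16 and the GTPase gene NOG1 at -0.15 in the authors' deposited table. Among ribosomal protein genes, RPL13B had -0.59, RPL24B -0.41, RPS22B -0.33 and RPL24A 0.22 in the authors' deposited table; 68 of the 103 have a near-identical copy and 56 contain an intron. Genes of the mitochondrial ribosome did not lie below, with a median of 0.015, 44 of 67 positive, inside the range of the random lists at percentile 67.1.

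The purine and Gcn4 lists lay below as well. Among lists given further on, ergosterol only just missed the bound, at percentile 2.54, while the medians of sulfur assimilation and thiamine lay well inside the range. Purine synthesis genes had a median of -0.073 (17 of 21 negative, percentile 0.26), with the IMP dehydrogenase gene IMD2 at -0.19, SHM2 at -0.15, ADE17 at -0.14 and ADE4 at -0.12 in the authors' deposited table. The Gcn4 list, mostly of amino acid synthesis genes, had a median of -0.048 (44 of 54 negative, percentile 0.98), with HIS6 at -0.77, the ornithine carbamoyltransferase gene ARG3 at -0.18, ILV5 at -0.15 and ASC1, which encodes a ribosome-associated protein and no biosynthetic enzyme, at -0.13 in the authors' deposited table. The Gcn4 list moved inside the middle 95% when random lists were matched on GC and codon adaptation (percentile 3.44), when intron-containing genes were left out (3.15) and among genes of 1000 nt or more (3.80).

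Genes of MATa and haploid cells had a median of -0.068, with 15 of 18 negative, at percentile 0.01. ASG7 stood at -0.18, STE2, which encodes the receptor for alpha factor, at -0.15, the endonuclease gene HO at -0.13 and FAR1, needed for arrest by pheromone, at -0.12 in the authors' deposited table. By mean this list lay inside the range of random lists, at percentile 10.9. Alpha cells are the other haploid cell type, the opposite mating type to the MATa strain. Their 7 genes with a value had a median of -0.013 and lay inside the range at percentile 36.9. STE3, the a-factor receptor gene, had -0.66 and MATALPHA1 1.06 in the authors' deposited table. MATALPHA1 has a near-identical copy, so its reads may come from that copy, and the read numbers of these genes are unknown. Without the 3 alpha cell genes that have a near-identical copy, the remaining 4 had a median of -0.47 at percentile 0.04.

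A few lists that stood apart did so weakly or with mixed signs. Respiratory chain and ATP synthase genes had a median of 0.023 (23 of 41 positive, percentile 98.8) but a mean of -0.033, with the cytochrome oxidase subunit gene COX4 at -2.14, QCR9 at -0.90, COX26 at 0.31 and NDI1 at 0.21 in the authors' deposited table; the list lay inside the range by mean (percentile 18.3), with matching on length only (89.5) and without matching (90.7), and above it under the other 4 settings, with a median of 0.081 over its 9 genes of 1000 nt or more (99.8). Meiosis and sporulation genes had a median of -0.012 (25 of 49 negative, percentile 2.18) but a mean of 0.090 at percentile 98.0, the opposite side; a zero set at the genes of highest codon adaptation shifts all genes alike and puts the median at 0.020 without moving its percentile. The meiosis list lay inside the range with matching on length only (percentile 8.71) and without matching (12.6), and its median was -0.025 over the 37 genes of 1000 nt or more (0.43). HOP2 stood at 6.73, HOP1 at -1.72, SPS2 at 1.14 and LOH1 at 0.96 in the authors' deposited table. The positive sign of the meiosis mean rests on HOP2, which contains introns. Likewise, the negative sign of the respiratory mean rests on COX4. Protein folding chaperones had a median of 0.013 (23 of 36 positive) at percentile 97.52, and the list lay inside the range under 6 of 7 alternative settings, at percentiles down to 70.4; without near-identical copies its median was 0.027 (98.8). Among chaperones, SSA4 had 0.11, SIS1 0.11, SSB2 -0.12 and SSB1 -0.10 in the authors' deposited table.

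Of the 34 lists fixed before the data were examined, 32 had at least 4 members with a value, and 16 of these lay outside the middle 95% of their random lists, 9 above and 7 below, where 1.6 would be expected by chance if the genes of a list varied independently. Of simulated lists with no shift added, 4.5% lay outside low and 3.0% high. Their values had been shuffled within the matching classes, so they check the procedure only. They do not show how often a list of genes that vary together would lie outside. The percentile describes this table only, since it measures spread across genes and not across cultures.

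**Figure D1:**
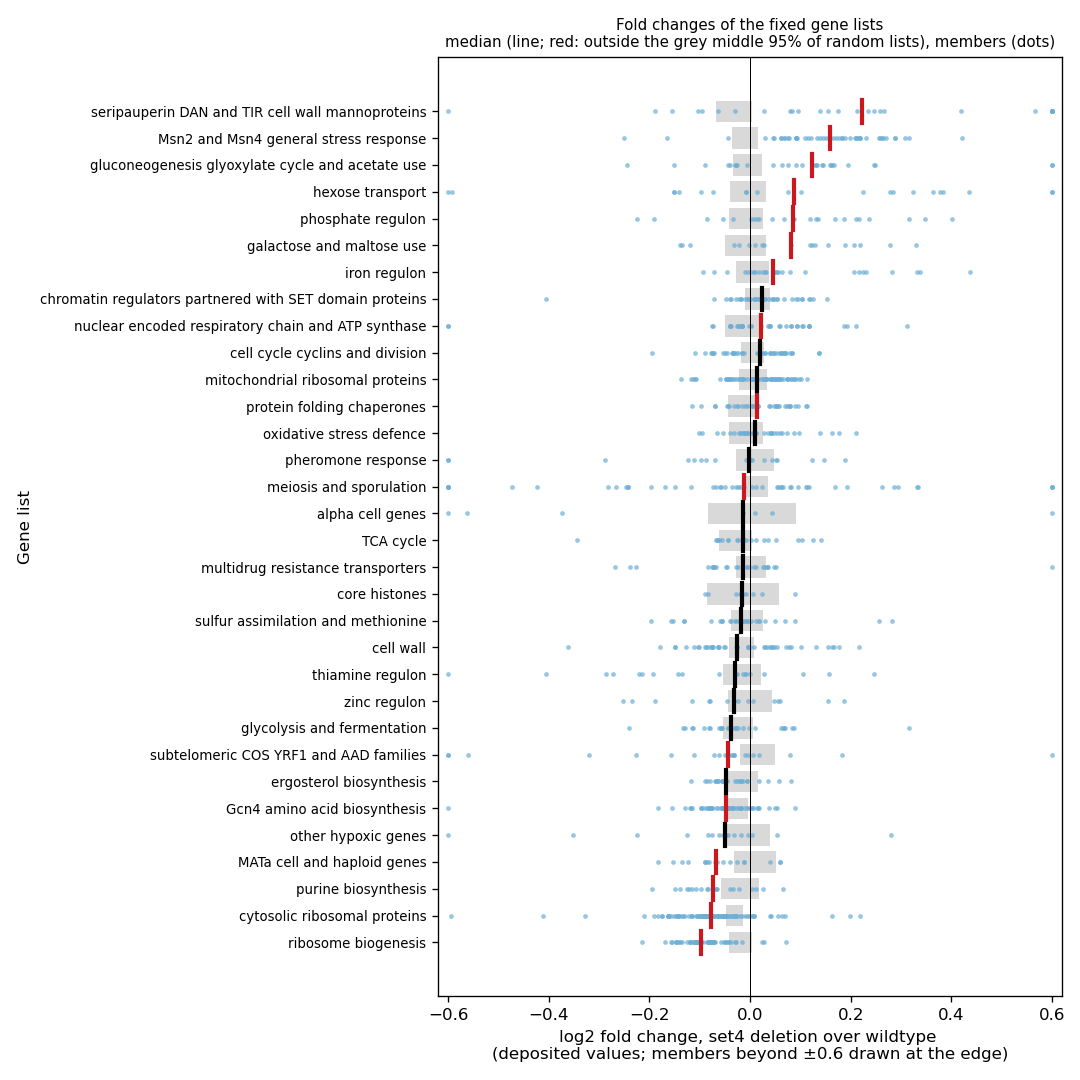
Each row is a list of genes fixed before the data were examined; dots are the members' deposited log2 fold changes (horizontal axis, deletion over wildtype, drawn at the edge beyond ±0.6), the thick vertical line is the list median and the grey bar the middle 95% of 10000 random lists matched on coding length and codon adaptation. The 16 medians outside the grey bar are red, from -0.097 for ribosome biogenesis to 0.22 for the mannoproteins.

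Other lists lay inside the range of random lists. Ergosterol synthesis genes had a median of -0.047 with 23 of 27 negative, at percentile 2.54, next to the bound of 2.5 and past it under 4 of 7 alternative settings; ERG2 stood at -0.12, the squalene epoxidase gene ERG1 at -0.09, ERG11 at -0.09 and ERG28 at 0.08 in the authors' deposited table. The other hypoxic genes had a median of -0.050 (14 of 17 negative, percentile 3.56), with the carbonic anhydrase gene NCE103 at -0.94, COX5B at -0.35, CYC7 at 0.28 and the fatty acid desaturase gene OLE1 at -0.22 in the authors' deposited table. Genes of oxidative stress defence had a median of 0.0097 (23 of 38 positive, percentile 85.8), with SRX1 at 0.21, the catalase gene CTT1 at 0.18, TSA2 at 0.16 and GPX1 at 0.14 in the authors' deposited table. Cell wall genes had a median of -0.025 at percentile 23.5, with SPS22 at -0.36, SPI1 at 0.22, UTR2 at -0.18 and PIR3 at 0.18 in the authors' deposited table. Chromatin regulators partnered with SET domain proteins had a median of 0.024 (26 of 39 positive, percentile 79.4); the deacetylase gene SIR2 had -0.40 and the other named members were SET6 at 0.15, SPP1 at 0.13 and HST1 at 0.12 in the authors' deposited table.

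Glycolysis and fermentation genes had a median of -0.039 (percentile 19.4) and tricarboxylic acid cycle genes -0.015 (83.8). Sulfur assimilation stood at a median of -0.017 (23.9), the zinc regulon at -0.031 (9.62) and the thiamine regulon at -0.029 (29.8). Pheromone response genes had a median of -0.0027 (23.8), core histones -0.016 (59.6), cell cycle genes 0.021 (90.4) and multidrug transporters -0.015 (13.6). By mean, 2 of these lists lay below their random lists, thiamine at -0.10 (percentile 0.13) and pheromone response at -0.14 (0.07). With matching on length only, glycolysis and fermentation (percentile 0.43), cell wall (0.90) and the other hypoxic genes (1.39) lay below too.

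Genes near chromosome ends, where Sir proteins silence transcription, formed a separate comparison because SET domain proteins have been studied at such regions. The 223 genes within 20 kb of an end had a median of -0.029, with 133 negative and 90 positive, below all matched random lists, against 0.0040 for the 5599 genes further in. A list of genes mostly of these regions, made up of the COS, YRF1 and AAD families with DDI2 and DDI3, had a median of -0.044 (18 of 23 negative, percentile 0.08), with COS12 at -1.13, AAD15 at -0.91, COS8 at 0.89 and DDI3 at -0.56 in the authors' deposited table. Of the 223 genes 112 have a near-identical copy, and without them the median of the rest was -0.010 at percentile 5.37, inside the range; the family list likewise lay inside, at percentile 7.37, over its 6 genes without a copy. The mean of the 223 genes was positive, at 0.0081, at percentile 59.8. A zero set at the genes of highest codon adaptation shifts all genes alike and puts the median at 0.0027 without moving its percentile, so the low place of these genes is relative to other genes. Values at 2-fold or more made up 6.73% of these genes and 0.964% of those further in.

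The coding genes with the extreme values outside multi-copy families were mostly very short. The highest were ATG44, a mitophagy gene (YIL156W-B, chromosome IX, 47690 to 47973), at 11.92, the meiotic gene HOP2 (YGL033W, chromosome VII, 435625 to 436401) at 6.73 and YMR141C (chromosome XIII, 549736 to 550044) at 4.17 in the authors' deposited table. They were followed by ECM23 at 2.89, YBR221W-A at 2.67, YKL183C-A at 2.64, YHL048C-A at 2.58, VBA3 at 2.38, YLR264C-A at 2.13 and YCL048W-A at 2.07 in the authors' deposited table. The lowest after SET4 were YNL067W-B (chromosome XIV, 499417 to 499557) at -7.27, YLR156C-A (chromosome XII, 472479 to 472610) at -4.14 and IRC13 (YOR235W, chromosome XV, 779870 to 780184) at -4.13 in the authors' deposited table. Next came YFR057W, which lies 0.873 kb from the end of chromosome VI, at -3.68, then YGL149W at -3.64, YBR298C-A at -3.43, YOR072W-B at -3.16, YOR029W at -3.04, YPL062W at -2.94 and YHR214C-D at -2.44 in the authors' deposited table. Of these 20 genes 18 belong to the shortest of 5 equal classes of coding length, of 612 nt or less, and ATG44 and HOP2 contain introns. YLR156C-A, YOR072W-B and VBA3 have a near-identical copy, so their values are uncertain.

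Among genes of 1000 nt or more with neither an intron nor a near-identical copy, the extremes were smaller. SMA2, which acts in spore membrane formation, had 1.81, YBR225W 1.23, the sporulation gene SPS2 1.14 and the glycerol symporter gene STL1 1.04 in the authors' deposited table. They were followed by YMR317W at 0.81, the budding landmark gene AXL2 at 0.66, the biotin transport gene BIO5 at 0.64, PGU1 at 0.62, PBI1 at 0.62 and POT1 at 0.60 in the authors' deposited table. At the low end stood YGL138C at -2.22, the meiotic chromosome axis gene HOP1 at -1.72 and YKR015C at -1.12 in the authors' deposited table. The next included the sporulation genes SPO74 at -0.91, SPO75 at -0.79, SPO77 at -0.65 and SSP1 at -0.47 in the authors' deposited table. The remaining low ones were STE3 at -0.66, YFL040W at -0.41 and SIR2 at -0.40 in the authors' deposited table. Genes of meiosis and spore formation stood at both ends, and they are normally silent in haploid cells growing on glucose. Whether they are more frequent here than among all genes of this kind was not tested. The meiosis and sporulation list itself was split, with 24 members positive and 25 negative.

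Transcripts other than coding genes were more widely spread. Values at 2-fold or more were held by 70 of 5823 coding genes, and made up 3.49% of 1918 transcripts assembled without a gene name, 21.0% of 609 other named reading frames and 27.0% of 163 tRNAs. The 81 small nucleolar and nuclear RNAs had 0 at this size. Of 13 ribosomal RNA entries, 8 lay at 2-fold or more lower and 1 higher, with a median of -1.10. The 18S entries RDN18-1 and RDN18-2 stood at -1.10 for both and the 25S entry RDN25-1 at -1.18, while the precursor entries RDN37-1 and RDN37-2 stood at -5.47 and -11.85 in the authors' deposited table. These RNAs are the target of the depletion kit. The entries are of several different RNAs, each with more than 1 copy, so the 13 values are not independent of each other. The single highest value of all, 29.17, belonged to the assembled transcript MSTRG.3067.1, and MSTRG.5188.1 stood at -10.18 in the authors' deposited table; neither has coordinates there. Among tRNAs, tL(UAG)J had 5.84 and tM(CAU)J1 -4.58 in the authors' deposited table.

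**Figure D2:**
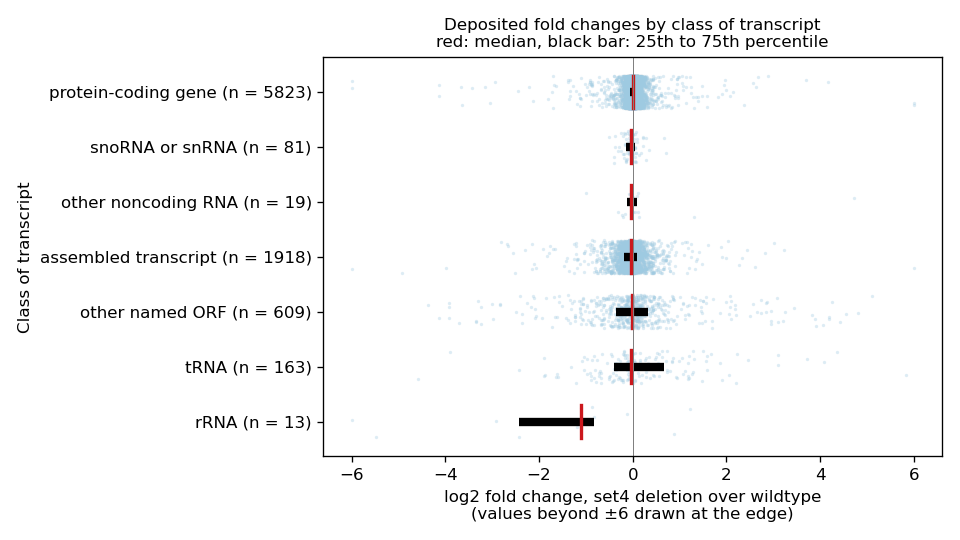
Each dot is a transcript, placed by its deposited log2 fold change (horizontal axis, deletion over wildtype, drawn at the edge beyond ±6) and by its class (vertical axis, with the number of transcripts); the red line is the median and the black bar runs from the 25th to the 75th percentile. Protein-coding genes cluster around 0.0034, while tRNAs, other named reading frames and rRNAs spread more widely.

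The series is about statistics for data with a spike. Whether these data have such a spike was not tested, since the table holds no test statistics. The distribution of all 8626 values, which pools classes of unlike spread, had a narrow centre and wide tails. Its median was -0.0018. Its width, set from the interquartile range as for a normal curve, was 0.108, against a standard deviation of 0.625. Beyond 3 such widths of the median lay 1134 transcripts, 13.1% of the table, where a normal curve of that width would place 23.3. At 2-fold or more there were 160 on each side.

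Size of value went with properties of the gene. In the shortest of the 5 length classes (78 to 612 nt) 4.55% stood at 2-fold or more (95% Wilson interval 3.49 to 5.90), against 0.344% (0.212 to 0.557) of the others. For genes with a near-identical copy the share was 4.10%, against 0.976% of genes without. Intron-containing genes had 2.68% and intron-free genes 1.15%, with intervals of 1.05 to 6.70 and 0.900 to 1.46 that overlap. These intervals treat genes as independent and cover counting error only.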

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

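All alternatives here were chosen after seeing the data, except the distances of 10 and 30 kb and the removal of named families near chromosome ends. The number of lists outside the middle 95% was 16 and ran from 12 to 17 over 7 alternatives: 17 with matching on length only (13 of the 16 kept), 14 on GC and codon adaptation (14 kept), 17 unmatched (13 kept), 14 by mean (11 kept), 15 without intron-containing genes (14 kept), 17 without near-identical copies (15 kept) and 12 of 28 lists among genes of 1000 nt or more (12 kept). In that last setting the mannoprotein and ribosomal protein lists had fewer than 4 members, and the chaperone and Gcn4 lists lay inside. Removing intron-containing genes or near-identical copies left the medians of all 16 lists within their bootstrap intervals. Some still moved: without near-identical copies hexose transport went from 0.088 to 0.045 and chaperones from 0.013 to 0.027. Setting 0 at the genes of highest codon adaptation, whose median was -0.032, shifts every gene and every random list alike, so it moves no percentile; by construction the meiosis and sporulation median becomes 0.020 and that near chromosome ends 0.0027.

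Leaving out SET4, 35 coding genes lay 2-fold or more higher and 34 lower. At 1.5-fold these were 69 and 73, at 1.2-fold 191 and 170, and read as natural logs 59 and 60. Over all transcripts they were 160 and 159. Among genes of 1000 nt or more they were 8 and 5, and without near-identical copies 22 and 31; fewer genes enter these last counts by construction. The median near chromosome ends was -0.029 and stayed negative within 10 kb (-0.039), within 30 kb (-0.012), without the named families (-0.030) and without near-identical copies (-0.010). The mean was 0.0081; the cause of the difference between mean and median was not tested.

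No paired analysis was possible because the table has no column per library. For the same reason other normalizations, count filters, tools, null distributions, pseudocounts, adjusted p thresholds, estimated correlations and leaving out replicates, all planned, were not run, nor were splits of the 6 libraries. With depth unknown, a large value from few reads cannot be told from one backed by many.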

Other observations

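All tests in this part were chosen after the results were seen. Lists inside the range of random lists still held single genes far from 0, and those named here were chosen after their values were seen, from the 4 furthest from 0 in their list. Among pheromone response genes, the nuclear fusion gene PRM3 stood at -1.35, FIG1 at -0.99 and PRM1 at -0.29, while PRM4 stood at 0.19 in the authors' deposited table. The alpha factor genes MF(ALPHA)1 and MF(ALPHA)2, made by the opposite mating type to the MATa strain, stood at -0.56 and -0.37 in the authors' deposited table. In the tricarboxylic acid cycle, the citrate synthase genes went both ways, with CIT3 at -0.34 and CIT1 at 0.14 in the authors' deposited table. Thiamine genes THI13 at -0.61 and SNZ2 at -0.41 in the authors' deposited table have near-identical copies. The polyamine transporter genes TPO1 and TPO2 stood at -0.27 and -0.23, and the sulfur genes MET2 and SUL2, the latter a sulfate permease gene, at 0.28 and 0.26, in the authors' deposited table.

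Coding genes without a value were unevenly spread. Of 271 nuclear coding genes with an intron, 122 had no value in the table used here, 45.0% (95% Wilson interval 39.2 to 51.0), against 57 of 5731 intron-free genes, 0.995% (0.769 to 1.29). Of the 138 cytosolic ribosomal protein genes, many of which carry introns, 103 had a value. Of the 19 coding genes of the mitochondrial genome, 0 had a value there. The values for intron-rich gene groups thus rest on part of the group.

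The intron pattern admits more than 1 reading. An intron-related step in alignment or in naming of assembled transcripts is a candidate explanation. The share of 45.0% against 0.995% is the pattern to be explained and is no separate evidence for it. Low expression, judged by codon adaptation, was argued against as the whole cause: intron-free genes of the same codon adaptation would give a share of 1.02%, and in all 5 classes of codon adaptation the intron-containing genes (40.2% to 54.5%) lay above the intron-free ones (at most 2.61%) with 95% Wilson intervals that do not overlap. Whether the missing genes are among the 1918 assembled transcripts could not be tested without coordinates, and no biological explanation was tested.

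Targets of Msn2 and Msn4 lay above, and ribosome biogenesis genes below, the other genes, a pairing known from the general response of yeast to stress and slower growth. Their medians differed by 0.255 (95% bootstrap interval 0.206 to 0.293), which restates why the lists were picked; an offset common to all genes moves no list relative to the others by construction. With the median of each stratum of codon use, GC and length taken out, the difference was 0.253 (0.208 to 0.295). Both lists had been picked for standing apart from random lists already matched on length and codon adaptation. That outcome was thus largely set beforehand and is no separate evidence against a trend with these properties. Earlier glucose depletion in the deletion cultures may contribute. Of 3 lists repressed by glucose, 2 lay above the middle 95% of random lists, gluconeogenesis and respiratory chain. The tricarboxylic acid cycle did not. The place of the respiratory list depended on matching by codon adaptation. It lay inside the range with matching on length only (percentile 89.5) and without matching (90.7), while gluconeogenesis stayed at percentile 100 in both. The respiratory mean had the opposite sign, which rests on COX4 at -2.14 in the authors' deposited table. The hexose transport list and the galactose and maltose list (percentile 99.98), not counted among the 3, lay above too. The gluconeogenesis list had 20 of 29 members positive, but FBP1 at -0.15 and MLS1 at -0.24 in the authors' deposited table. Glucose depletion therefore remains open. That the SET4 deletion itself sets the pairing of stress and ribosome lists is a hypothesis. A difference in growth stage or culture density between a few of the 6 libraries stays equally open. Both are untested.

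The mannoprotein genes had the highest list median, and most share sequence with near-identical copies. Reads split between copies do not account for the 7 genes without a copy, whose median was 0.247, above all matched random lists. Apart from PAU5 these 7 are DAN and TIR genes. They therefore cannot tell whether split reads shaped the values of the other PAU genes, and that stays open. Noise of few reads stays open, since the table has no counts and the list was picked for its high values. Oxygen limitation in the deletion cultures would raise the other hypoxic genes as well, but these had a median of -0.050 (95% bootstrap interval -0.083 to -0.018), with 14 of 17 negative. That interval treats genes as independent, and against matched random lists the median lay inside the range, at percentile 3.56. These genes were thus not raised as a set, which cannot exclude an oxygen effect limited to the mannoprotein genes. An effect of SET4 deletion on these genes is a hypothesis to follow up with counts per library, since a single library that stands apart for another reason stays open too.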
